A study of Arabidopsis thaliana with 48 samples.

How the data were processed

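RNA-seq of whole Arabidopsis thaliana seedlings was measured in 48 libraries. Seedlings grew on agar plates in long days (LD, 16 h of light) or short days (SD, 8 h of light), and RNA was taken after 11 days in LD and 14 days in SD, per the labels' protocols. The labels name 9 genotypes. They are wild type, the single mutants ino80 and arp5, the multiple mutants nfrkb1/2/3, uch1/2 and atx4/5;jmj24, and 3 transgenic lines in the ino80 background. INO80-FL carries full-length INO80, INO80-(1-550) its N-terminal part and INO80-(335-1540) its C-terminal part; the last 2 are abbreviated INO80N and INO80C, and INO80-FL is written INO80FL. Set 1 holds repeats 1 and 2 of all 9 genotypes in both day lengths, which makes 36 libraries in 18 groups. Set 2 holds repeats 3 and 4 of 6 genotypes in SD, which makes 12 libraries. The labels give no sequencer for set 2, and no age apart from the 14 days that the protocols state for SD.

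Libraries were single-ended with 50-bp reads, per the labels' protocols. The authors aligned reads with HISAT2 2.2.0 to TAIR10 and used edgeR, whose version is not stated, per the submitters' processing notes. The program that assigned reads to genes, its annotation, its strand setting and its filters are not recorded. The deposited values are a gene-level signal, read counts adjusted to a common library size, separately for each set, with 32548 loci. The unit was read from the values. They are not whole numbers, columns sum to 18867187 to 22653356 in set 1 and 20080952 to 22921363 in set 2, and low values cluster near whole multiples of a step. The step, the value of 1 read, was 0.903 to 1.11 in set 1 and 0.918 to 1.05 in set 2, which puts depth at 20.06 to 21.04 M reads per library in set 1 and 21.72 to 21.94 M in set 2, so a value of 1 stands for about 1 read. At least 86.2% of low values in set 1 and 91.7% in set 2 lay within 0.1 of a whole multiple, too few to rebuild counts, so no count model was run. The tables were normalized apart, so values of set 1 and set 2 were not pooled. The 10 most abundant genes took 5.55% to 9.15% of a library in set 1 and 5.41% to 6.64% in set 2.

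The planned test assumed raw counts. Its stated fallback for normalized values was used instead. Values were transformed as log2(value + 1), genes with a value of at least 1 in at least 2 libraries were kept, and limma's moderated test with a mean-variance trend was fitted with 1 mean per group. The libraries of a set were fitted together, because 2 libraries per group leave few degrees of freedom. This left 25638 genes with 18 residual degrees of freedom in set 1, and 24458 genes with 6 in set 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of weakly expressed genes. Means are of normalized read counts with the SD of 2 libraries unless another n is given. SE is the standard error of a log2 fold change. The software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8).

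The test was checked on simulated counts drawn around the real group means, with ino80 given the wild-type mean. Then 50, 100 and 50 genes with a wild-type mean of at least 10 were changed by a log2 of 0.5, 1 and 2 in size. These are far fewer than the genes called in the real data, so the rates below need not hold there. For ino80 against wild type in LD of set 1, 46% of genes changed by a log2 of 0.5 were called, 84% at 1 and 96% at 2, with 61 false calls among 216. Of those false calls, 14 had a mean of at least 10 and 43 a mean under 1. For ino80 in set 2, 34%, 68% and 82% were called, with 81 false calls among 207, of which 9 had a mean of at least 10 and 61 a mean under 1. These figures come from 26242 and 24774 simulated genes. Genes at a mean of a few reads are therefore not named as single findings unless a fixed rule below picked them.

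Each line was compared with wild type of its own set and day length, each transgenic line also with ino80, INO80N with INO80C, and wild type in SD with wild type in LD. An interaction contrast tested whether an effect differed between day lengths in set 1. Calls shared with ino80 were counted per direction and set beside the number that independent lists would share. In 20 simulations every group, ino80 included, was given the wild-type mean of its set and day length. They measured the correlation and covariance that shared controls give. Restoration was measured in set 1 on genes called in ino80 in set 2, so that choice and measurement used different libraries. Its value is the least-squares slope through 0 of the line's log2 fold change on that of ino80, where 0 means wild-type level and 1 the ino80 level. Noise of the ino80 libraries lowers a slope, so a slope below 1 alone does not show restoration. A second value is the share of genes nearer to wild type than to ino80, which also counts genes that moved past wild type. Slopes from 1 line, 1 ino80 and 1 wild-type library at a time gave its SD.

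Lists of 24 gene groups were written down before the data were examined, as were the test, the comparisons, the rule for named genes and part of the other settings. Of their members, 401 were kept and 2 were left out because the reference gives their loci another symbol. The lists cover INO80 complex subunits, H3K4 methyltransferase and H2A.Z genes, flowering time, the circadian clock, light signalling, photosynthesis antenna and Rubisco small subunit genes, flavonoids, salicylic acid, jasmonate, ethylene, auxin, abscisic acid and cold, heat shock, touch, DNA damage, cell cycle, phosphate starvation, iron deficiency, glucosinolates, dark and sugar starvation, DNA methylation and silenced loci, root markers, floral organ identity and seed markers. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01. Its p was adjusted by Benjamini-Hochberg over all 384 list tests against wild type in set 1, over 120 in set 2, over 120 for the interactions, and over the 24 lists within each other comparison. Camera was also run with a correlation estimated per list.

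Named genes were the 10 targeted genes, and called genes picked per comparison with wild type. A picked gene had a symbol, non-overlapping libraries and, in either group, a mean of at least 5 per M of the library total. Those that changed most were taken, 10 in each direction for ino80 in set 1 and 5 elsewhere. To these come up to 4 members of a discussed list with the smallest p, and FLC, FT, SOC1 and CO. Of the 190 genes so named outside ino80 in set 1, 100 are left out of the text. Most are left out because their call or size changed without 1 library, or to avoid a mere list of names. Symbols come from the TAIR10.1 annotation, which matched all 32548 loci and gives a symbol for 10804. It also gave gene order, strand and overlaps between genes. The annotation does not say which locus carries which NFRKB number, so that assignment is uncertain.

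The other settings fixed at that time were no low-value filter, a pseudocount of 0.1, the repeat number as a block, fits of 1 day length alone, calls at an adjusted p under 0.01, genes chosen in the other day length, estimated list correlations and leaving out each library in turn. Equal library totals, median-of-ratios rescaling, quantile normalization, voom weights, a mean value of at least 10, a seed-transcript covariate, crossed repeat numbers and separate wild-type libraries were added after seeing the data. A DESeq2 model, DESeq2 size factors and a joint fit of both sets need counts and were not run.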

Results

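The 48 libraries profile mRNA of wild-type seedlings and of seedlings labelled as mutants of INO80 chromatin remodeler subunits or partners, or as carrying a full-length or truncated INO80 transgene in the ino80 mutant. The design asks which transcripts depend on INO80 and its partners in each day length, and which of these respond to the N-terminal or C-terminal part of INO80 alone. Each group of set 1 has 2 libraries, and SD groups of 6 genotypes have 2 more in set 2. Library totals ranged from 18867187 to 22653356 normalized reads in set 1 and from 20080952 to 22921363 in set 2. Replicate libraries correlated at r = 0.987 to 0.994 across genes in the 24 groups, where genes are not independent replicates.

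The targeted genes were examined first. INO80 (AT3G57300, chromosome 3) read 1580 in wild type in LD and 861.7 ± 111.8 in ino80 (SD, n = 2), a log2 fold change of -0.88 (SE 0.0956, adjusted p = 3.5e-07). Its level in ino80 was 44.7% of wild type in SD of set 1 and 59.2% in set 2, so transcript reads remain over the mutated gene. In LD, INO80 reached 4785 ± 240.3 in INO80FL, 6429 ± 172.8 in INO80N and 12090 ± 762.8 in INO80C. The locus overlaps AT3G57290, and these totals do not separate a truncated transcript from a complete one. NFRKB1 fell to 19.41 ± 16.4 from 539.2 ± 12.9 in nfrkb1/2/3 in LD, NFRKB3 fell to 48.12 ± 8.37 from 274.6 ± 1.21, and NFRKB2 kept 64.7% of the wild-type level. NFRKB2 was at 81.6% in nfrkb1/2/3 in SD of set 1, near its 83.9% in ino80 and 77.6% in uch1/2, and in set 2 at 54.3%, so in SD of set 1 its level does not set the labelled triple mutant apart. The log2 fold change of NFRKB1 was -5.01, with -4.08 and -5.94 when the first or the second nfrkb1/2/3 library was left out. In uch1/2, UCH2 fell to 73.55 ± 1.63 from 519.4 ± 19.3 and UCH1 to 85.24 ± 6.78 from 192.2 ± 16.5. In libraries labelled atx4/5;jmj24, ATX4 read 96.79 ± 15.8 against 388 ± 3.35 in SD of set 1 and had log2 fold changes of -1.90 and -1.85 in LD and set 2, and JMJ24 had -1.75, -2.22 and -2.08 in LD, SD of set 1 and set 2. ATX5 in those libraries was not called in LD (299 ± 45.9 against 347 ± 8.76; log2 -0.38, adjusted p = 0.028 without the second atx4/5;jmj24 library) or set 2 (364.5 ± 36.1 against 301.4 ± 46.1), and fell by 1.18 in SD of set 1 (adjusted p = 8.5e-09).

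**Figure D1:**
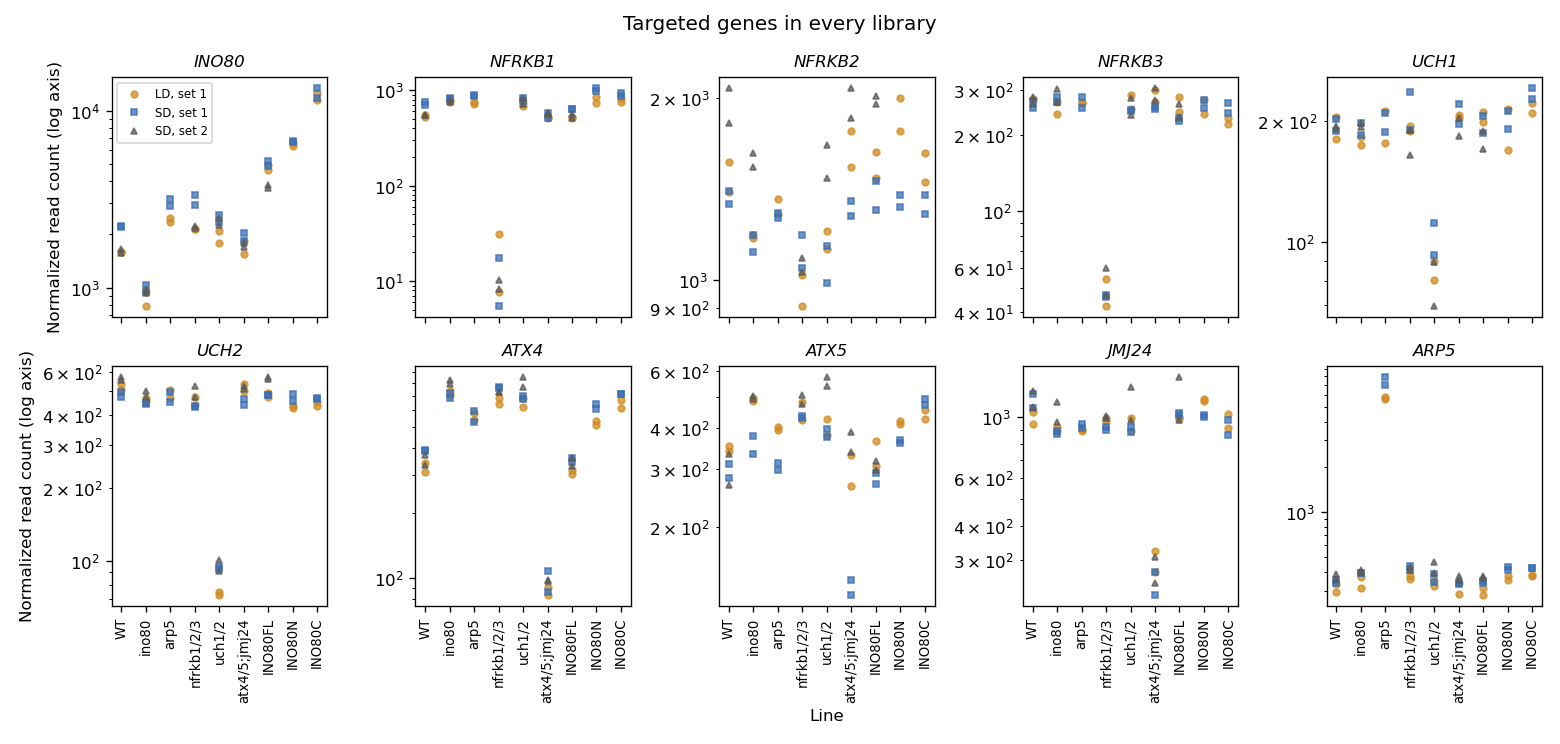
Normalized read count (log axis) of the 10 targeted genes in every library, by line, with circles for LD of set 1, squares for SD of set 1 and triangles for SD of set 2. ARP5 lies far above wild type in libraries labelled arp5, at a mean of 5736 in LD against 313.5 in wild type.

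ARP5 (AT3G12380) went against its label. It read 5736 ± 122 in libraries labelled arp5 in LD against 313.5 ± 28.6 in wild type, 18.3-fold higher (adjusted p = 2.5e-20), and 7460 ± 672.6 against 346.2 ± 12.2 in SD (adjusted p = 7.2e-21). The next gene downstream on the same strand, AT3G12370, rose by 7.36 in LD (46000 ± 695.4 against 280 ± 17.1, adjusted p = 6.7e-24) and by 7.71 in SD. ITN1, which faces ARP5 and AT3G12370 from the opposite strand, had log2 fold changes of -1.23 in LD and -1.67 in SD. AT3G12390, beside the 5' end of ARP5, changed by 0.10 (adjusted p = 0.41) and 0.00. AT3G12370, AT3G12390 and ITN1 are outside the rule for named genes and were chosen after their values were seen. The arp5 label therefore names these libraries here without a statement on ARP5 function.

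**Figure D2:**
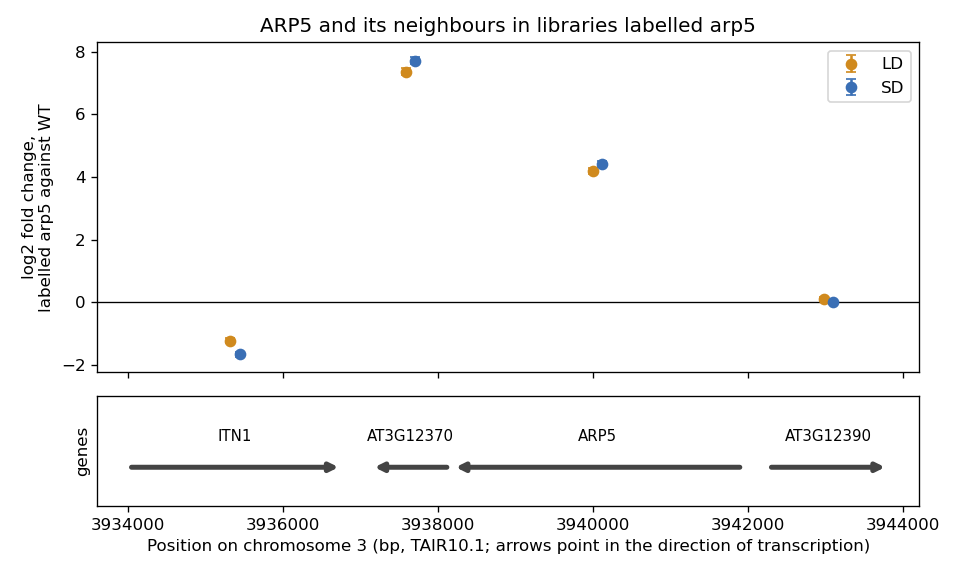
Log2 fold change with SE (top) and gene map (bottom, chromosome 3, TAIR10.1) for ARP5 and its neighbours in libraries labelled arp5 against wild type, LD and SD of set 1. AT3G12370 and ARP5 rose in both day lengths, by 7.36 and 4.19 in LD, and AT3G12390 stayed near 0.

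In LD, the jasmonate-linked aminotransferase gene TAT3 rose in ino80 to 146.8 ± 4.83 from 11.54 ± 0.756, a log2 fold change of 3.56 (SE 0.657, adjusted p = 2.3e-04). The DNA damage genes GMI1 and NAC044 rose by 2.48 (SE 0.163, adjusted p = 2.3e-10) and 2.82 (SE 0.335, adjusted p = 1.2e-06). The amino acid sensor gene ACR1 fell to 23.65 ± 8.52 from 380.5 ± 12.6 (SE 0.2697 on the log2 scale, adjusted p = 2.8e-10). ACR1 was also low in INO80FL, at a log2 of -3.47, -4.17 and -4.21 in LD, SD of set 1 and set 2. Its fall in ino80 can therefore not be assigned to loss of INO80. The beta-glucosidase gene BGLU5 fell, at a log2 of -2.96, and so did the demethylase gene DML3 at -2.64. Also lower were HDA2 at -4.82, ANNAT7 at -3.34, NGA2 at -3.15, OTP84 at -3.05, PYD4 at -2.82, PGL5 at -2.79 and CYP71B24 at -2.68, with adjusted p from 1.5e-09 to 2.7e-05. HDA2 overlaps AT5G26030, so its reads cannot be assigned to 1 of them with certainty. The other 9 genes the rule names among those that rose are left out, because leaving out 1 library moved their fold by more than 1.5 times or ended the call; they include the defensin PDF1.2 and the seed storage genes CRA1 and CRU3.

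Among the fixed lists in LD, photosynthesis antenna and Rubisco genes fell in ino80, 21 of 22 over all genes and 22 adjusted over the list alone, with a median of -0.75 (camera adjusted p = 2.1e-16; adjusted p = 0.43 with an estimated correlation). LHCB1.2 fell to 53920 ± 283.6 from 146100 ± 2560, and LHCB2.3 and LHCB2.2 had log2 fold changes of -1.22 and -1.04; members of these families are near-identical copies that can share reads. Heat shock genes rose, 10 of 17 (13 adjusted over the list alone), median 1.11, camera adjusted p = 5.8e-05, and adjusted p = 0.41 with an estimated correlation. DNA damage genes rose, 9 of 20 (9 adjusted over the list alone), median 0.30, camera adjusted p = 1.6e-04, and adjusted p = 0.41 with an estimated correlation. Light signalling genes fell, 11 of 23 with 2 higher (14 and 3 adjusted over the list alone), camera adjusted p = 0.0087, and adjusted p = 0.53 with an estimated correlation. Clock genes fell, 8 of 19 with 2 higher (10 and 2 adjusted over the list alone), camera adjusted p = 0.012, and adjusted p = 0.53 with an estimated correlation. Cell cycle genes rose, 6 of 22 (6 adjusted over the list alone), camera adjusted p = 0.0054, and adjusted p = 0.55 with an estimated correlation.

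The seed marker list passed camera in ino80 in LD with 7 of 13 higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.02), but not without the first wild-type library (adjusted p = 0.069), and adjusted p = 0.63 with an estimated correlation. Floral organ genes rose, 3 of 8 (3 adjusted over the list alone, adjusted p = 0.021), led by PI at 47.78 ± 0.493 against 8.79 ± 2.98 and SEP3 at 729.7 ± 75 against 208.1 ± 20.7. That list call ended without the second wild-type library (adjusted p = 0.12), and gave adjusted p = 0.51 with an estimated correlation. Salicylic acid genes, 11 of 25 higher and 3 lower (11 and 4 adjusted over the list alone), gave 0.028, and 0.14 without the first wild-type library or 0.051 without the first ino80 library; adjusted p = 0.56 with an estimated correlation. Flavonoid genes, 5 of 18 higher and 1 lower (5 and 1 adjusted over the list alone), gave 0.029, and 0.14 without the first wild-type or 0.21 without the second ino80 library; adjusted p = 0.70 with an estimated correlation. With equal library totals none of these 4 lists passed, at adjusted p of 0.19, 0.12, 0.11 and 0.15 in the order given. The other 14 lists did not pass in ino80 in LD. Their calls higher and lower were 5 and 0 for jasmonate genes, 1 and 0 for root markers, 1 and 4 for dark and sugar starvation genes, 0 and 4 for abscisic acid genes, 0 and 3 for iron deficiency genes, 1 and 3 for INO80 complex genes, 1 and 3 for ethylene genes and 0 and 1 for phosphate starvation genes, with the same numbers adjusted over the list alone. They were 2 and 7 for flowering time genes (2 and 8 adjusted over the list alone), 1 and 2 for touch genes (1 and 3), 4 and 3 for auxin genes (4 and 4), 3 and 3 for H3K4 and H2A.Z genes (4 and 3), 2 and 1 for DNA methylation genes (2 and 2), and 4 and 5 for glucosinolate genes (5 and 8). Median and mean differed in sign for ethylene genes (0.06 and -0.04) and for H3K4 and H2A.Z genes (-0.09 and 0.04).

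Over all genes in LD, 7341 of 25638 were called in ino80, 3372 higher and 3969 lower, of which 1502 changed by at least 2-fold. The split depended on scaling. With equal library totals, a choice made after seeing the data, the median over all genes moved to 0.13 and the split to 6490 higher and 2461 lower.

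The other mutants in LD shared several of these genes. The Argonaute gene AGO9 rose in uch1/2 to 198.2 ± 15.4 from 3.303 ± 0.00381 (log2 5.53, SE 0.401, adjusted p = 1.2e-09). In nfrkb1/2/3 the auxin gene GH3.3 rose by 3.25 (SE 0.335) and the kinase gene PERK12 by 2.58 (SE 0.175), and HOL2 fell, with a log2 fold change of -3.09, OTP84 with -3.01 and SEP4 with -2.63. In uch1/2, ANNAT7 was lower at -3.64, DML3 at -3.45, NGA2 at -3.26 and HOL2 at -2.90. In libraries labelled arp5, FDM2 stood at -1.80, emb2746 at -1.60, OTP84 at -1.95 and SEP4 at -1.83, and PORA rose by 1.77. In libraries labelled atx4/5;jmj24, IAA29 rose to 612.6 ± 217.7 from 95.54 ± 11.9 and BT2 by 2.40, while HOL2 fell to 18.4 ± 0.695 from 309.1 ± 8.75, and GLR2.7, SEP4 and the fructosidase gene FRUCT5 fell with log2 fold changes of -3.29, -3.07 and -2.97. ATX4 itself rose in ino80, nfrkb1/2/3 and uch1/2, to 2.21, 2.03 and 1.99 times wild type in LD.

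Photosynthesis genes fell in nfrkb1/2/3 and uch1/2 in LD, 22 of 22 in each (22 and 22 adjusted over the list alone), with camera adjusted p of 2.9e-14 and 6.1e-12; adjusted p = 0.49 and 0.51 with an estimated correlation. In libraries labelled arp5, 7 fell (19 adjusted over the list alone) with adjusted p = 2e-09, which quantile normalization raised to 0.39; adjusted p = 0.53 with an estimated correlation. Auxin genes rose in nfrkb1/2/3, 16 of 19 with 1 lower (17 and 1 adjusted over the list alone), adjusted p = 2.3e-10, and adjusted p = 0.38 with an estimated correlation. They rose in libraries labelled atx4/5;jmj24, 15 of 19 (15 adjusted over the list alone), adjusted p = 4e-14, and adjusted p = 0.27 with an estimated correlation. Jasmonate genes rose in the same libraries, 12 of 19 (14 adjusted over the list alone), adjusted p = 2.5e-10, and adjusted p = 0.41 with an estimated correlation. VSP2 reached 5479 ± 223.7 there, against 1388 ± 138.3 in wild type. In uch1/2, 9 jasmonate genes rose (12 adjusted over the list alone), adjusted p = 1.1e-04, and 11 salicylic acid genes with 1 lower (12 and 1 adjusted over the list alone), adjusted p = 0.0017; adjusted p = 0.53 and 0.51 with an estimated correlation.

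In LD, 6534 genes were called in nfrkb1/2/3 (2870 higher, 3664 lower), 7301 in uch1/2 (3288 and 4013), 3409 in libraries labelled atx4/5;jmj24 (1510 and 1899) and 2538 in libraries labelled arp5 (932 and 1606). With equal library totals the higher and lower calls were 6591 and 2283, 5662 and 2655, 2261 and 1502, and 2944 and 819. The uch1/2 count was 4718 without its first library. For the atx4/5;jmj24 label it was 1793 or 2121 without the first or second wild-type library and 2237 without the second line library. For the arp5 label leaving out any of the 4 libraries gave 1039 (first wild type) to 1554 (second wild type).

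**Figure D3:**
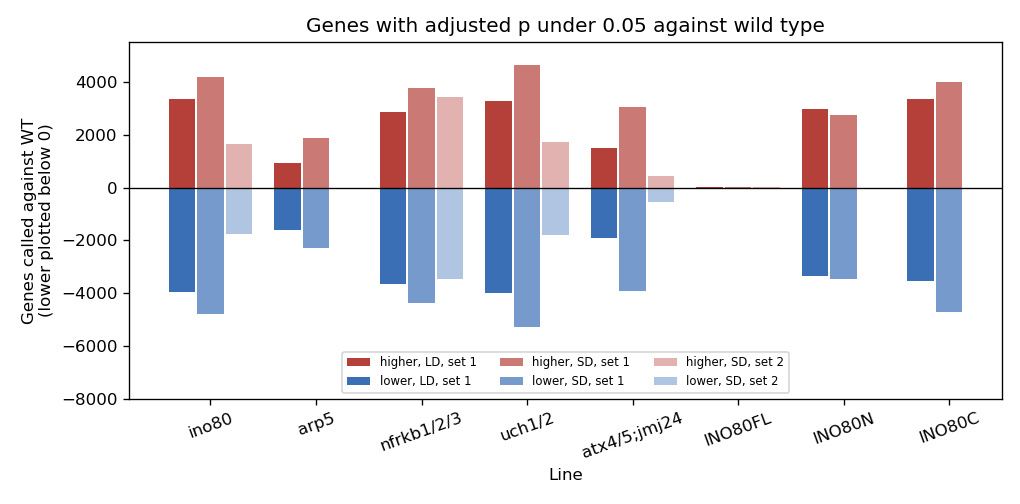
Genes called higher (above 0) and lower (below 0) than wild type, per line, in LD of set 1, SD of set 1 and SD of set 2. Lines without set 2 libraries have 2 bars, and INO80FL has 31, 33 and 13 calls.

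In SD of set 1, the transporter gene UMAMIT14 rose in ino80 to 1201 ± 0.804 from 78.65 ± 0.938 (log2 3.92, SE 0.314, adjusted p = 2.7e-09). GMI1 rose by 2.93 (SE 0.163, adjusted p = 1.4e-11) and PERK12 by 3.33 (SE 0.175, adjusted p = 6.9e-12). NAS2 rose by 2.99, TH8 by 2.92, SEP3 by 2.84 and SYN1 by 2.74; GMI1 and SYN1 overlap other annotated genes. The chlorophyll breakdown gene NYC1 fell to 224.2 ± 9.20 from 1683 ± 77.6 (log2 -2.90, SE 0.0993, adjusted p = 2.6e-15), and ACR1 fell by 3.69 (SE 0.2697, adjusted p = 6.4e-10). LTI65 fell to 195.5 ± 34.3 from 3685 ± 1277, and BBX32, PAP24, AGL24, SEP4, CBF2 and EMB2423 had log2 fold changes of -3.41, -3.35, -3.34, -3.32, -3.00 and -2.95. The remaining 4 genes of the rule, BAM5, LURP1, ARD3 and WRKY40, changed in size by more than 1.5 times without 1 library or lost the call with voom weights.

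AGO9 rose in uch1/2 in SD as well, to 209 ± 31 from 2.647 ± 0.771, and CGA1 and RVE1 had log2 fold changes of -3.13 and -3.11. NYC1 fell by 2.99 in nfrkb1/2/3. In libraries labelled arp5, EMB2423, emb2746 and FDM2 stood at -2.65, -1.99 and -1.95, and AGL24 fell to 25.76 ± 1.08 from 150.5 ± 7.56. In libraries labelled atx4/5;jmj24, HOL2 fell to 28.47 ± 1.54 from 331.5 ± 2.04, and SEP4, GLR2.7 and TRFL8 stood at -3.86, -3.46 and -2.97.

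Root markers rose in SD of set 1 in ino80, 11 of 16 (14 adjusted over the list alone, adjusted p = 6.3e-05), in nfrkb1/2/3, 14 (14 adjusted over the list alone, adjusted p = 7.5e-06), in uch1/2, 16 (16 adjusted over the list alone, adjusted p = 1.3e-08), and in the atx4/5;jmj24 label, 11 (15 adjusted over the list alone, adjusted p = 4.3e-07). In that order these calls gave adjusted p = 0.49, 0.41, 0.41 and 0.41 with an estimated correlation. The root list also passed with a positive median in INO80FL in SD of set 1, against the same wild-type libraries. The rise of root markers can therefore not be assigned to the mutants alone. The nitrate transporter NRT2.1 reached 209.6 ± 11.3 in ino80 against 34.22 ± 16.2 in wild type. Clock genes fell in ino80, 12 of 19 with 1 higher (12 and 1 adjusted over the list alone), adjusted p = 1.2e-04, and adjusted p = 0.41 with an estimated correlation. RVE1 fell to 1289 ± 63.9 from 7666 ± 59.98 and CCA1 to 8785 ± 39.1 from 17260 ± 48.5 in ino80. Floral organ genes rose in ino80, 5 of 8 (5 adjusted over the list alone), adjusted p = 0.0059, and adjusted p = 0.41 with an estimated correlation; SEP3 reached 176.3 ± 17.59 against 23.75 ± 1.81. Abscisic acid and cold genes fell in ino80, 8 of 17 (10 adjusted over the list alone), median -1.24, adjusted p = 0.006, and adjusted p = 0.70 with an estimated correlation. Heat shock genes fell in the atx4/5;jmj24 label, 9 of 17 (11 adjusted over the list alone), adjusted p = 4.8e-04, and adjusted p = 0.47 with an estimated correlation.

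Photosynthesis genes fell in nfrkb1/2/3 in SD of set 1, 20 of 22 (21 adjusted over the list alone), adjusted p = 1.2e-10, and adjusted p = 0.53 with an estimated correlation. In ino80, 15 fell (16 adjusted over the list alone) with adjusted p = 1.1e-04, which quantile normalization raised to 0.41; adjusted p = 0.68 with an estimated correlation. The counts of calls in SD of set 1 were 8989 for ino80 (4191 higher, 4798 lower), 8161 for nfrkb1/2/3 (3769 and 4392), 9934 for uch1/2 (4644 and 5290), 6975 for the atx4/5;jmj24 label (3053 and 3922) and 4149 for the arp5 label (1875 and 2274; 2624 in all with log2 CRA1 as a covariate). With equal library totals they split as 7229 and 2738, 7977 and 2286, 7808 and 2861, 6041 and 2186, and 3990 and 968, and the median over all genes moved by 0.13 to 0.18. The atx4/5;jmj24 label had 4342 calls without the second wild-type library and 4523 or 4616 without its own first or second. The arp5 label had 1750 without the second wild-type library and 2066 or 2588 without its own first or second, and nfrkb1/2/3 had 5367 without its own second.

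Set 2 repeats the SD comparisons in separate libraries, wild type included. In ino80, GMI1 rose to 664.4 ± 6.79 from 82.46 ± 1.05 (log2 3.00, SE 0.0968, adjusted p = 1e-06), PERK12 by 4.01, FRO5 by 3.79 and SYN1 by 3.32. ACR1 fell to 30.88 ± 0.12 from 391.2 ± 52.4, and SEP4, HDA2 and the iron response gene BHLH100 had log2 fold changes of -3.39, -5.13 and -4.91. AGO9 rose in uch1/2 to 351.7 ± 19.1 from 1.055 ± 0.00438 (adjusted p = 4.1e-07). In the atx4/5;jmj24 label, MRN1 rose by 3.14 and BCAT7 by 2.88, and SEP4, CRK18 and DML2 fell, at -3.97, -2.99 and -2.63. Iron deficiency genes fell in ino80, 8 of 12 with 1 higher (9 and 1 adjusted over the list alone), median -1.76, adjusted p = 1.9e-05, and adjusted p = 0.31 with an estimated correlation. They fell in uch1/2, 8 with 1 higher (11 and 1 adjusted over the list alone), median -2.17, adjusted p = 4.8e-05, and adjusted p = 0.31 with an estimated correlation. Photosynthesis genes fell in nfrkb1/2/3, 22 of 22 (22 adjusted over the list alone), adjusted p = 4.1e-14, and adjusted p = 0.21 with an estimated correlation. Root markers rose there, 14 of 16 (16 adjusted over the list alone), adjusted p = 8.6e-09, and adjusted p = 0.21 with an estimated correlation. The root list also passed with a positive median in INO80FL of set 2, so its rise cannot be assigned to nfrkb1/2/3 alone. DNA damage genes rose in nfrkb1/2/3, 8 of 20 (11 adjusted over the list alone), adjusted p = 8.2e-04, and adjusted p = 0.21 with an estimated correlation.

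Set 2 gave 3424 calls for ino80 (1661 higher, 1763 lower), 6903 for nfrkb1/2/3 (3422 and 3481), 3548 for uch1/2 (1745 and 1803) and 999 for the atx4/5;jmj24 label (438 and 561). With the log2 level of the seed transcript CRA1 as a covariate, which takes 1 degree of freedom, the counts were 1261, 2550, 2193 and 353. CRA1 read 156.8 and 211.6 in the ino80 libraries of set 2 against 19.81 and 10.63 in wild type. Equal library totals gave 2345 and 1292, 6073 and 2087, 2331 and 1337, and 561 and 450. Leaving out any of the 4 libraries gave 1534 (without ino80 repeat 4) to 1862 for ino80, 1688 (without uch1/2 repeat 3) to 2036 for uch1/2 and 336 (without the label's repeat 3) to 407 for the atx4/5;jmj24 label. For nfrkb1/2/3 the count was 3824 without its repeat 3 and 4547 without wild-type repeat 3. Of genes called in SD of set 1, 84.9% (7577 of 8928) had the same sign in set 2 in ino80, 84.1% in nfrkb1/2/3, 82.5% in uch1/2, 76.3% in the atx4/5;jmj24 label and 93.8% (30 of 32) in INO80FL. Adjusted over the list alone, 3018 genes of ino80 passed with the same sign and 101 with the opposite sign, 4160 and 227 in nfrkb1/2/3, and 3210 and 131 in uch1/2. The share for INO80FL was 81.25% without its repeat 4 and 81.82% without wild-type repeat 1.

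SOC1, a flowering promoter, fell in ino80 in LD (305.3 against 558.4, log2 -0.88, SE 0.236, adjusted p = 0.0069), in SD of set 1 (226 against 416.9, adjusted p = 0.0048) and in set 2 (log2 -0.52, adjusted p = 0.03). Without the first ino80 library of that day length the adjusted p was 0.079 in LD and 0.071 in SD, and in set 2 any of the 4 libraries left out gave 0.079 to 0.14. In uch1/2, SOC1 changed by -1.40 in LD and -0.91 in SD of set 1, the latter with adjusted p = 0.068 without the first uch1/2 library. In nfrkb1/2/3 it changed by -0.98 in LD (adjusted p = 0.09 without the second nfrkb1/2/3 library) and -0.80 in set 2. It was not called in nfrkb1/2/3 in SD of set 1 (-0.43, adjusted p = 0.17), in uch1/2 of set 2 (-0.43, adjusted p = 0.061) or in libraries labelled arp5 or atx4/5;jmj24. FLC was not called against wild type, with log2 fold changes from -1.44 to 1.06, though INO80FL in LD gave -2.67 (adjusted p = 0.02) without its first library. Against ino80, FLC was lower in INO80FL in LD (-2.19, adjusted p = 0.0028), in SD of set 1 (-1.95, adjusted p = 0.008) and in set 2 (-2.19, adjusted p = 0.014). Each of these FLC calls was lost in some fits without 1 library. Such a fit leaves 1 library in a group and has less power, so the loss does not show dependence on that library. FLC read 17.22 and 2.248 in the INO80FL libraries in LD, 11.37 and 4.245 in SD of set 1, and 12.34 and 5.236 in set 2. CO was called in none of these comparisons. FT passed in uch1/2 of set 2 (5.99 ± 1.26 against a group listed at 0, adjusted p = 0.021), and not when any of the 4 libraries was left out (0.069 to 0.11). In INO80N in SD it passed when the first line library was left out (adjusted p = 0.046). AGL24 fell in ino80 in LD to 2.954 ± 0.0132 from 35.15 ± 6.01, SPL9 fell by 1.23 on the log2 scale and MAF5 rose by 2.33.

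Calls shared with ino80 were counted in the same direction. In LD, ino80 shared 5175 of the 7301 uch1/2 calls, where independent lists would share 432.4 higher and 621.2 lower. It shared 4632 of 6534 with nfrkb1/2/3 (377.5 and 567.2), 2011 of 2538 with the arp5 label (122.6 and 248.6), and 1821 of 3409 with the atx4/5;jmj24 label (198.6 and 294). In SD of set 1 the shared calls were 7429 in uch1/2, 6440 in nfrkb1/2/3, 3493 in the arp5 label and 4711 in the atx4/5;jmj24 label. In the simulations ino80 was unchanged too, so there were almost no calls to share. The at most 1 call shared there is therefore no chance level for the observed numbers. Within a set, the simulated fold changes correlated at r = 0.50 through the common wild-type libraries. The observed correlations across genes in LD were 0.795 for uch1/2, 0.745 for nfrkb1/2/3, 0.628 for the arp5 label and 0.506 for the atx4/5;jmj24 label. The covariances were 0.306, 0.273, 0.183 and 0.170 against a simulated 0.0435, which leaves differences of 0.263, 0.230, 0.139 and 0.126. Part of the excess may come from the shared controls. With ino80 from set 2 and the lines from SD of set 1, no library was shared. There 2275 calls coincided with uch1/2, where independent lists would share 317 higher and 380.8 lower. With nfrkb1/2/3 2100 coincided (257.1 and 315.3), with the arp5 label 1405 (127.8 and 163.5) and with the atx4/5;jmj24 label 1299 (207.7 and 281.6). Calls in opposite directions numbered 115, 93, 47 and 232 in this order. Without the first or second wild-type library in LD the shared calls were 858 or 1249 for the arp5 label and 929 or 1123 for the atx4/5;jmj24 label, and 902 or 1132 without the first or second library labelled arp5. Without the second wild-type library in SD they were 1521 and 2856, and the arp5 label had 1760 or 2276 without its own first or second. Across the sets, any library of set 2 left out lowered them, furthest to 1129 (ino80 repeat 3) for uch1/2 and, without ino80 repeat 4, to 1054 for nfrkb1/2/3, 778 for the arp5 label and 639 for the atx4/5;jmj24 label. The arp5 label there also had 790 without wild-type repeat 2 and 851 without its own repeat 1.

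Few genes were called in INO80FL against wild type. In INO80FL, ACR1 fell in all 3 comparisons, in LD to 33.96 ± 9.12 from 380.5 ± 12.6 (log2 -3.47, SE 0.2697, adjusted p = 2.2e-08), and with -4.17 and -4.21 in SD of set 1 and set 2. QQS rose to 335 ± 5.60 from 28 ± 9.66 in LD (log2 3.58, SE 0.352, adjusted p = 2.1e-06), and by 2.95 and 3.06 in SD. ROS1, listed in the annotation as DML1, fell by 0.80 in SD of set 1. The list of iron deficiency genes passed in LD with no single call (5 higher adjusted over the list alone), median 0.73, adjusted p = 3.7e-05, and adjusted p = 0.51 with an estimated correlation. Of 24 lists, 5 passed in LD, 7 in SD of set 1 and 4 in set 2, and 0 of these with an estimated correlation. They include touch genes in LD (median 0.41, adjusted p = 0.021) and flavonoid genes in SD of set 1 (median 0.34, adjusted p = 0.022), both of which hinged on single libraries, and root markers in SD of set 1 (median 0.40, adjusted p = 1.5e-08) and set 2 (median 0.29, adjusted p = 1.2e-05). Calls numbered 31 in LD (10 higher, 21 lower), 33 in SD of set 1 (21 and 12) and 13 in set 2 (6 and 7), and 2362, 2066 and 1467 genes had an unadjusted p under 0.05, where 1282, 1282 and 1223 would if no gene differed. With equal library totals LD gave 11 higher and 12 lower. Without 1 library the LD count was 12 (INO80FL repeat 2 left out) or 16 (wild-type repeat 1 left out). In SD of set 1 it was 15 or 77 without INO80FL repeat 2 or 1, and 57 without wild-type repeat 1. In set 2 any library left out gave 5 (without wild-type repeat 3) to 8, and the CRA1 covariate gave 8. Fitting LD alone gave 15 in LD, and voom weights gave 15 in SD of set 1.

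INO80N and INO80C each differed from wild type in LD. In INO80N, IAA29 rose to 1454 ± 288.7 from 95.54 ± 11.9 (log2 3.90, SE 0.174, adjusted p = 3.8e-13), ACS8 by 3.60, GH3.3 by 3.32, BT2 by 3.19 and IAA5 by 3.18. HMGB1 fell to 172.5 ± 41.3 from 1522 ± 8.73 (adjusted p = 7.5e-16; it overlaps AT3G51870), and ACR1, BBX18 and OTP84 fell with log2 fold changes of -3.37, -2.38 and -2.33. In INO80C, GH3.3 rose by 3.39, IAA5 by 3.53 and QQS by 3.38, and ACR1, MLP328 and CYP71B24 fell, at -3.98, -3.90 and -3.35. Auxin genes rose in INO80N, 17 of 19 with 1 lower (17 and 1 adjusted over the list alone), median 1.31, adjusted p = 6.9e-17, and adjusted p = 0.22 with an estimated correlation. Glucosinolate genes fell in INO80N, 15 of 21 with 2 higher (15 and 2 adjusted over the list alone), adjusted p = 1.9e-07, and adjusted p = 0.41 with an estimated correlation. Heat shock genes rose in INO80C, 14 of 17 (14 adjusted over the list alone), median 1.39, adjusted p = 6.6e-09, and adjusted p = 0.29 with an estimated correlation. In LD, CCA1 read 1025 in INO80N against 2342 in wild type, and LHY 599.2 against 1442. TOC1 read 652.5 against 417.3 and PRR5 149.8 against 96.66. The labels give no time of harvest. Comparisons with wild type in LD, the auxin results included, may therefore carry a difference in time of day, which was not tested. LD calls were 6352 for INO80N (2991 higher, 3361 lower) and 6902 for INO80C (3348 and 3554), and 4503 or 4546 for INO80C without its second library or the first wild-type library. Equal library totals split INO80N into 4394 and 2345.

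In SD of set 1, IAA29 rose in INO80N by 3.09 and NAS2 by 2.63, and CBF2 and ACR1 fell, at log2 -3.82 and -3.47. In INO80C, PERK12 rose by 4.22 and GMI1 by 2.98, and BBX32 and CBF2 fell, at -4.35 and -4.04. Phosphate starvation genes fell in INO80N, 9 of 14 (9 adjusted over the list alone), median -1.36, adjusted p = 2.7e-05, and adjusted p = 0.55 with an estimated correlation. They fell in INO80C, 10 of 14 (10 adjusted over the list alone), adjusted p = 6.5e-04, and adjusted p = 0.67 with an estimated correlation. SQD2 read 818.5 ± 288.9 and 902.3 ± 225.6 in the fragment lines against 2631 ± 369.2 in wild type. Calls were 6220 for INO80N (2763 higher, 3457 lower; 5938 and 1938 with equal library totals) and 8702 for INO80C (4004 and 4698; 7240 and 2730). The INO80N count was 3842 without the second wild-type library and 4032 without its own first.

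Against ino80 in LD, the full-length transgene raised LHCB1.2 to 146100 ± 9760 from 53920 ± 283.6. Photosynthesis genes rose, 21 of 22 (21 adjusted over the list alone), median 0.71, adjusted p = 3.1e-15, and adjusted p = 0.28 with an estimated correlation. In INO80N the same list rose, 20 of 22 with 1 lower (20 and 1 adjusted over the list alone), adjusted p = 4.2e-10, and adjusted p = 0.26 with an estimated correlation. In INO80C it rose, 19 of 22 (22 adjusted over the list alone), adjusted p = 5.5e-16, and adjusted p = 0.20 with an estimated correlation. Auxin genes rose above ino80 in INO80N, 17 of 19 (18 adjusted over the list alone), median 1.38, adjusted p = 7.2e-18, and adjusted p = 0.014 with an estimated correlation. They rose in INO80C, 14 of 19 (15 adjusted over the list alone), median 1.08, adjusted p = 5e-14, and adjusted p = 0.046 with an estimated correlation. IAA2 reached 4522 ± 135.4 in INO80N and 2674 ± 122.3 in INO80C against 1721 ± 95 in ino80. Dark and sugar starvation genes rose in INO80N, 4 of 10 (5 adjusted over the list alone), adjusted p = 0.0015, and adjusted p = 0.028 with an estimated correlation. SEN1 reached 3017 ± 599.2 against 424.1 ± 32.4. Flavonoid genes fell in INO80N against ino80, 13 of 18 (16 adjusted over the list alone), median -1.45, adjusted p = 2.6e-10, and adjusted p = 0.056 with an estimated correlation.

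In set 2, iron deficiency genes rose in INO80FL against ino80, 9 of 12 with 1 lower (10 and 1 adjusted over the list alone), median 2.31, adjusted p = 2.4e-06, and adjusted p = 0.23 with an estimated correlation. Against ino80, LD calls were 7891 in INO80FL (4189 higher, 3702 lower), 6571 in INO80N (3504 and 3067) and 5327 in INO80C (3055 and 2272). Equal library totals gave 2820 and 5898, 2702 and 4090, and 1549 and 4799, with the median over all genes at -0.10, -0.04 and -0.12. In SD of set 1 the calls were 6966 in INO80FL (3838 and 3128; 2210 and 5849 with equal library totals), 3237 in INO80N (1557 and 1680) and 1655 in INO80C (771 and 884), and in set 2 INO80FL had 2672 (1405 and 1267; 1137 and 1705). Without the first line library the LD counts were 5052, 3958 and 2703 and the SD counts 4454, 1247 and 283. Leaving out an ino80 library in LD gave 4312 for INO80N (the second), and 2862 or 3486 for INO80C (the first or second). In SD it gave 4586 for INO80FL (the second), 1669 or 1270 for INO80N and 590 or 417 for INO80C. In set 2, INO80FL had 1070 or 1106 without ino80 repeat 3 or 4 and 1535 without its own repeat 3. INO80N and INO80C differed from each other in 4897 genes in LD (2353 higher in INO80N, 2544 lower; 3165 and 1476 with equal library totals) and in 1987 in SD. The LD count was 3015, 3083 or 3177 without INO80C repeat 2, INO80C repeat 1 or INO80N repeat 2, and in SD any library left out gave 749 (INO80N repeat 1) to 1098.

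Restoration was measured on the 3419 genes called in ino80 in set 2. The slope on the ino80 change was 0.077 ± 0.034 (SD of single-library slopes) for INO80FL in LD and 0.170 ± 0.059 in SD. For INO80N it was 0.601 ± 0.046 and 0.619 ± 0.021, and for INO80C 0.765 ± 0.037 and 0.804 ± 0.038. In the mutants it was 0.872 and 0.921 for uch1/2, 0.784 and 0.836 for nfrkb1/2/3, 0.527 and 0.597 for the arp5 label, and 0.40 and 0.517 for the atx4/5;jmj24 label. INO80C lay near nfrkb1/2/3, which is no transgenic line, so its distance from 1 alone does not show restoration. INO80N lay between nfrkb1/2/3 and the arp5 label in both day lengths, so the same limit holds for INO80N. INO80FL was nearer to wild type than to ino80 in 87.1% of the genes in LD and 86.5% in SD, INO80N in 46.9% and 39.2%, INO80C in 38.4% and 24.2%, and uch1/2 in 17.61% and 15.2%. The share was 22.73% and 18.89% in nfrkb1/2/3, 47.65% and 40.6% in the arp5 label, and 67.89% and 49.96% in the atx4/5;jmj24 label. INO80N and INO80C lay below both of these labels, which are no transgenic lines. The shares of the fragment lines alone therefore do not show restoration. Without its second library INO80FL had a slope of 0.043 in LD. The order of the 3 transgenic lines exceeded the SD of single-library slopes in both day lengths. In LD, 833 genes were nearer to wild type in both fragment lines, 771 in INO80N alone, 479 in INO80C alone and 1336 in neither, where independence would give 615.5 in both. In SD the numbers were 534, 808, 295 and 1782, where independence would give 325.4 in both. The fragment lines share the wild-type and ino80 libraries, which raises the number in both.

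**Figure D4:**
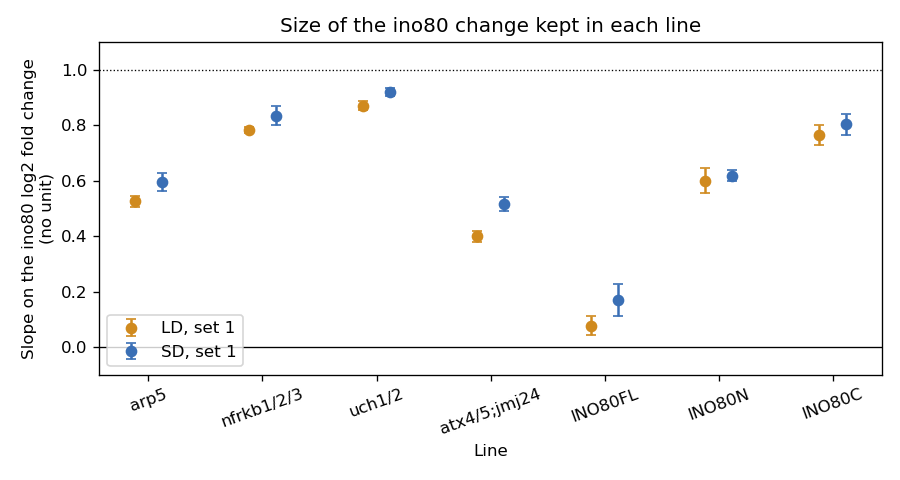
Slope of each line's log2 fold change on that of ino80 (no unit) over 3419 genes called in ino80 in set 2, measured in LD and SD of set 1, with the SD of single-library slopes. INO80FL lies nearest 0 (wild type), INO80N at 0.601 and 0.619, and INO80C at 0.765 and 0.804; the dotted line at 1 is the ino80 level.

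Wild type in SD was compared with wild type in LD, which differ in age by design (14 and 11 days). The anthocyanin genes DFR and LDOX fell, DFR to 5.819 ± 2.28 from 1118 ± 235.5 (log2 -7.38, SE 0.606, adjusted p = 1.8e-09) and LDOX by a log2 of -6.43. UF3GT, CYP82C4 and NUDT24 fell with log2 fold changes of -7.23, -6.81 and -6.62. ASG4 rose by 5.16, HAI1 by 4.97, LTI65 by 4.82, HSFA6A by 4.55 and BT1 by 4.30. LHY rose to 18010 ± 433.4 from 1443 ± 141.5 and CCA1 to 17260 ± 48.5 from 2341 ± 303. Flavonoid genes fell, 12 of 18 with 1 higher (13 and 2 adjusted over the list alone), adjusted p = 9.1e-06, and adjusted p = 0.28 with an estimated correlation. Cell cycle genes fell, 17 of 22 (19 adjusted over the list alone), adjusted p = 8e-06, and adjusted p = 0.25 with an estimated correlation. Heat shock genes rose, 12 of 17 with 1 lower (12 and 1 adjusted over the list alone), adjusted p = 4.5e-05, and adjusted p = 0.25 with an estimated correlation. In all, 9645 genes were called (4698 higher, 4947 lower).

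The clock genes also differed between the sets at the same day length. In wild type in SD, CCA1 was higher in set 1 than in set 2 by a log2 of 8.61 and LHY by 10.75, and TOC1 and PRR5 were lower, at -4.34 and -5.62. Over 19762 genes the median difference was -0.09. CCA1 ran from 7515 to 17300 across all SD libraries of set 1 and from 29.07 to 55.93 across set 2. Values for the repeat in set 2 therefore carry this difference as well.

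**Figure D5:**
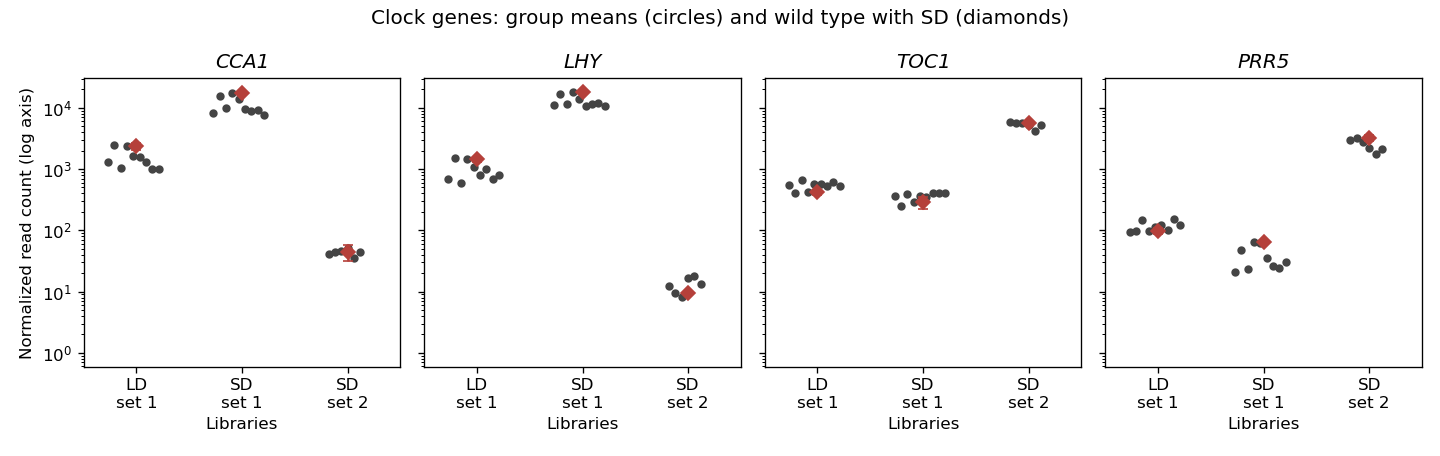
Normalized read count (log axis) of CCA1, LHY, TOC1 and PRR5 in LD of set 1, SD of set 1 and SD of set 2; circles are group means and diamonds are wild type with SD. CCA1 and LHY are high in SD of set 1 and low in SD of set 2, and TOC1 and PRR5 are the reverse.

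The interaction asked whether an effect differed between day lengths in set 1. In libraries labelled atx4/5;jmj24, ATX5 differed by -0.96 (SE 0.137, adjusted p = 1.4e-04) and JMJ24 by -0.47, and UCH2 differed by 0.44 in uch1/2 (adjusted p = 0.003). Heat shock genes had a lower effect in SD than in LD in uch1/2, 10 of 17 (13 adjusted over the list alone), median -1.52, camera adjusted p = 3.3e-09, and adjusted p = 0.22 with an estimated correlation. The list also passed in the other 4 lines at the preset correlation, with 5 of 17 lower in ino80 (median -0.93, adjusted p = 1.7e-04), 0 in the arp5 label (-0.67, adjusted p = 3.3e-05), 4 in nfrkb1/2/3 (-0.73, adjusted p = 1.3e-04) and 5 in the atx4/5;jmj24 label (-0.92, adjusted p = 5e-05), and in none of them with an estimated correlation (adjusted p = 0.32 in each). All 5 contrasts use the same wild-type libraries, in which heat shock genes are higher in SD, so part of the common direction can come from these. Root markers had a higher effect in SD in uch1/2, 8 of 16 (15 adjusted over the list alone), median 0.87, adjusted p = 4.5e-08, and adjusted p = 0.32 with an estimated correlation. They passed in the same direction in the arp5 label with 0 of 16 called (median 0.56, adjusted p = 3.1e-07), the atx4/5;jmj24 label with 4 (0.79, adjusted p = 5.6e-08) and ino80 with 0 (0.52, adjusted p = 7.1e-04), and not with an estimated correlation (adjusted p = 0.32, 0.32 and 0.40). In nfrkb1/2/3 root markers did not pass at the preset correlation (median 0.31, adjusted p = 0.081). Auxin genes had a lower effect in SD in nfrkb1/2/3, 8 of 19 (13 adjusted over the list alone), median -0.66, adjusted p = 2e-10, and adjusted p = 0.26 with an estimated correlation. They passed at the preset correlation in uch1/2 with 6 of 19 lower and 1 higher (median -0.64, adjusted p = 5e-06), the atx4/5;jmj24 label with 5 lower (-0.50, adjusted p = 1.3e-04), the arp5 label with 0 (-0.19, adjusted p = 0.0023) and ino80 with 4 (-0.15, adjusted p = 0.029). With an estimated correlation the adjusted p was 0.32, 0.37, 0.53 and 0.67 in this order, and in the arp5 label and ino80 leaving out single libraries also raised it above 0.05. In all 5 contrasts root markers had a positive median and auxin genes a negative one. Part of these common directions can also come from the shared wild-type libraries. The fall of photosynthesis genes in ino80 was weaker in SD, 6 of 22 (10 adjusted over the list alone), median 0.35, adjusted p = 1.2e-07, and adjusted p = 0.61 with an estimated correlation. Interaction calls numbered 1886 in ino80, 1385 in nfrkb1/2/3, 2496 in uch1/2 and 1863 in the atx4/5;jmj24 label, and the counts were 851, 720, 1256 and 880 without the second wild-type library in SD. Without the second wild-type library in LD they were 1069, 769, 1565 and 1134, and without the first 1160 in ino80, 1637 in uch1/2 and 1117 in the atx4/5;jmj24 label. Leaving out 1 line library gave 1001 to 1207 in ino80 (any of the 4), 879 or 826 in nfrkb1/2/3 (the first in LD or SD), 1413 or 1436 in uch1/2 (the second in LD or SD), and 1101 or 1049 in the atx4/5;jmj24 label (the first or second in SD). Equal library totals split uch1/2 into 1527 higher and 884 lower, against 1208 and 1288, and the atx4/5;jmj24 label into 1079 and 669, against 774 and 1089. In the arp5 label 2 genes were called (0 to 8 in other settings), 2210 had an unadjusted p under 0.05 (1282 if no gene differed), and leaving out 1 library gave from 0 to 25 calls, the most without the first wild-type library in SD.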

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

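The tests on the ARP5 region, on the clock genes and on the seed transcripts were chosen only after the results were seen. Effects that differ between day lengths were tested by an interaction contrast in limma, fixed in advance. It called 1886 genes in ino80, 1385 in nfrkb1/2/3, 2496 in uch1/2, 1863 in libraries labelled atx4/5;jmj24 and 2 in libraries labelled arp5. Among targeted genes, UCH2 differed by 0.44 in uch1/2 (SE 0.0885, adjusted p = 0.003), which means a weaker fall in SD. In libraries labelled atx4/5;jmj24, ATX5 differed by -0.96 (SE 0.137, adjusted p = 1.4e-04) and JMJ24 by -0.47 (SE 0.124, adjusted p = 0.021), a stronger fall in SD of set 1. In SD of set 2, ATX5 stood at 120.9% of wild type under the same label. Its fall is thus limited to SD of set 1 and cannot be taken as an effect of short days. Day length is tied to age here, 11 days in LD and 14 days in SD. Clock genes also differed between the day lengths in wild type of set 1, with CCA1 at 2342 in LD and 17260 in SD, and no harvest time is given. The contrast covers day length, age and any difference in time of day together.

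Targeted and flowering genes were checked for a single library far from the other 3 in the groups that have 4 SD libraries, with Dixon's ratio against its 95% critical value. Of 84 groups, 4 lay above it. Chance alone does this in about 1 in 20 groups, so the number is no excess. In INO80FL the ratio was 0.8571 for JMJ24 (978.6, 1019, 1040 and 1409, repeat 4 highest) and 0.8721 for CO (9.349, 15.6, 15.66 and 16.52, repeat 3 lowest). In nfrkb1/2/3 it was 0.9349 for NFRKB3 (46.09, 46.76, 46.98 and 59.78, repeat 3 highest) and 0.9769 for FT (0.862, 0.8949, 0.9299 and 3.808, repeat 4 highest). These groups join 2 sets that were normalized apart, and each distant library belongs to set 2.

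ARP5 was 18.27-fold above wild type in libraries labelled arp5 in LD and 21.45-fold in SD. Overexpression from another place in the genome would leave the neighbours near wild type, but AT3G12370, next downstream on the same strand, rose by at least 7.36 on the log2 scale in both day lengths. Transcription that starts in an insertion inside ARP5 and reads on into AT3G12370 needs AT3G12390, at the other end, to stay near 0, and its change was at most 0.1. An insertion in ARP5 is therefore a candidate explanation that may also bear on ITN1, which changed by -1.23 and -1.67. A mislabelled line, the position of an insertion and whether any ARP5 protein is made stay open.

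In SD, CCA1 and LHY were high in set 1 and low in set 2, and TOC1 and PRR5 were the reverse. Separate normalization of the 2 tables would shift all genes alike, but the median of 19762 genes moved by -0.09 in wild type where CCA1 moved by 8.61. If the 2 sets were harvested at different times of the day, opposite moves of the 2 pairs of genes by more than 2 follow in each genotype, and all 6 showed them. A harvest at another time of day is thus a candidate explanation, found and tested on the same libraries. The labels give no time of harvest, and for set 2 no age apart from that of the SD protocol. No genotype separates the sets, so no biological explanation was tested.

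Seed storage transcripts were high in part of the libraries. CRA1 read 100 or more in 0 of 12 wild-type and INO80FL libraries (1.535 to 76.4) and in 19 of 36 others (1.099 to 1901). Seed material carried along by chance, alike in all lines, argues for equal shares, which differed (two-sided Fisher's exact test, p = 0.0013). The test takes replicates of a group as independent libraries, so its p does not measure a difference between lines. Levels also varied within a line. In nfrkb1/2/3, CRA1 ran from 3.722 to 10.81 in set 1 and read 452.7 and 170.6 in set 2. A level set by the line alone argues for like replicates, but 7 of the groups had replicates that differed by more than 10 times with 1 added to each value, 1 of 6 in wild type and INO80FL and 6 of 18 in the others. With nothing added, 1 of 6 and 7 of 18 did. Seed or embryo tissue whose amount depends on the line and on the sampled seedlings may contribute, and this mixed case was not tested.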

How the results depend on the processing

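Equal library totals, median-of-ratios rescaling, quantile normalization, voom weights, a mean value of at least 10, log2 CRA1 as a covariate, crossed repeat numbers and separate wild-type libraries were tests chosen only after results were seen. A DESeq2 model, DESeq2 size factors and a joint fit of both sets were not run, because they need counts. The 2303 results of single genes gave 31661 values over the settings: 29118 stayed on the same side of the threshold in the same direction, 2491 no longer passed, 48 newly passed and 4 reversed. The 816 list tests gave 33264 values, of which 32285 stayed, 605 no longer passed, 371 newly passed and 3 reversed. Leaving out a library accounts for 1761 of the lost gene calls, the CRA1 covariate for 196 and equal library totals for 153. The CRA1 covariate also reversed 2 gene results. Counts of calls stayed within 1.5 times in 404 of 513 refits, and 94 of the other 109 came from leaving out a library. Median-of-ratios rescaling moved no count of calls by more than 1.5 times. Where no construction of the setting explains a change, the cause was not tested.

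The repeat number as a block gave 7403 calls for ino80 in LD. In set 2 it gave 4212 against 3424 for ino80, 7827 against 6903 for nfrkb1/2/3, 4328 against 3548 for uch1/2, 1303 against 999 for the atx4/5;jmj24 label, 12 against 13 for INO80FL and 3513 against 2672 for INO80FL against ino80. The block moved none of the 36 counts by more than 1.5 times. Deviations of libraries with the same number correlated at a median r of 0.012 over 153 pairs of groups in set 1 (-0.415 to 0.352) and 0.27 over 15 pairs in set 2 (-0.19 to 0.454). In set 1, 27 of the 153 pairs lay over 0.1. In set 2, the 10 pairs without the atx4/5;jmj24 label lay at 0.181 to 0.454 and the other 5 under 0.1. Same-numbered libraries of these 5 genotypes thus deviated together, which is a hint from the data and not the design. The labels name no shared batch or day and not every pair lay over 0.1, so the fit without the block was kept in both sets. The block ended the calls of 9 gene results and 2 list results, and 3 gene results and 11 list results newly passed with it. In LD, wild type and the atx4/5;jmj24 label correlated at -0.131, and crossing their numbers gave 3513 calls.

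Reversals were as follows. With the CRA1 covariate the seed list in the arp5 interaction gave adjusted p = 0.98 with the opposite sign, and EPR1 and OLEO2 in SD of the arp5 label gave -0.20 and 0. PSBO1 in SD of the arp5 label gave 0 with quantile normalization, and UCH2 in nfrkb1/2/3 in SD gave 0.03 with equal library totals. In INO80FL, the touch list in LD gave 0.95 without wild-type repeat 1 and ran from 5.6e-06 to 0.95 with 1 library left out. The flavonoid list in SD gave 0.30 without INO80FL repeat 2 and ran from 1.2e-07 to 0.30. The cause was not tested.

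The CRA1 covariate takes 1 degree of freedom from the fit, and in set 2 it partly follows the line. With it the count of calls was 2624 for the arp5 label in SD of set 1. In set 2 the counts were 1261 for ino80, 2550 for nfrkb1/2/3, 2193 for uch1/2, 353 for the atx4/5;jmj24 label and 8 for INO80FL. A fit of the same day length alone, with fewer libraries, gave 15 calls for INO80FL in LD, and voom weights gave 15 for INO80FL in SD of set 1. The 2 interaction calls of the arp5 label became 8 without a low-value filter, 6 with a pseudocount of 0.1, 4 with equal library totals, 5 with quantile normalization, 1 with voom weights, 0 with a mean value of at least 10 and 1 with the CRA1 covariate. With the correlation estimated per list, 0 of the 117 lists passing against wild type in set 1 and 0 of the 43 in set 2 passed; camera's estimates take the members' own correlation into account.

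Calls at an adjusted p under 0.01 are fewer by construction. In LD they shared with ino80 954 genes in the arp5 label, 2949 in nfrkb1/2/3, 3294 in uch1/2, 890 in the atx4/5;jmj24 label, 1847 in INO80N and 2230 in INO80C. In SD the numbers were 1773 in the arp5 label, 2789 in the atx4/5;jmj24 label, 2857 in INO80N and 4065 in INO80C, within set 1. With ino80 from set 2 they shared 557 in the arp5 label, 894 in nfrkb1/2/3, 931 in uch1/2, 468 in the atx4/5;jmj24 label, 635 in INO80N and 831 in INO80C. Slopes on genes so chosen were 0.551 for the arp5 label, 0.807 for nfrkb1/2/3 and 0.895 for uch1/2 in LD, and 0.474 for the atx4/5;jmj24 label in SD. The share with the same sign in set 2 was 87.87% for ino80, 86.6% for nfrkb1/2/3, 85.71% for uch1/2 and 79.67% for the atx4/5;jmj24 label.

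With separate wild-type libraries, no common library adds to both axes, but each axis also rests on a single wild-type library. The effects of these changes were not told apart. Slopes in this setting were lower. In LD they were 0.479 for the arp5 label, 0.728 for nfrkb1/2/3, 0.814 for uch1/2, 0.356 for the atx4/5;jmj24 label, 0.55 for INO80N, 0.71 for INO80C and 0.043 for INO80FL. In SD they were 0.55, 0.782, 0.865, 0.473, 0.572, 0.752 and 0.136 in the same order. The INO80FL slope fell from 0.077 in LD, the largest move in proportion. Genes chosen in the other day length gave 0.815 for nfrkb1/2/3, 0.429 for the atx4/5;jmj24 label and 0.726 for INO80C in LD, and 0.578 for the atx4/5;jmj24 label and 0.66 for INO80N in SD. A pseudocount of 0.1, which widens the folds of low genes, gave 0.547 for the arp5 label, 0.767 for nfrkb1/2/3, 0.444 for the atx4/5;jmj24 label and 0.134 for INO80FL in LD, and 0.898 for uch1/2 and 0.542 for the atx4/5;jmj24 label in SD. A mean value of at least 10 gave 0.378 for the atx4/5;jmj24 label in LD and 0.938 for uch1/2 in SD, and voom weights 0.799 for nfrkb1/2/3 in LD.

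Covariances with ino80 in LD, for the arp5 label, nfrkb1/2/3, uch1/2 and the atx4/5;jmj24 label in this order, were 0.4847, 0.6296, 0.6945 and 0.4926 with a pseudocount of 0.1, 0.2424, 0.3466, 0.387 and 0.2327 with voom weights, and 0.1377, 0.2252, 0.2554 and 0.119 with a mean value of at least 10. Without a low-value filter the last 3 were 0.2555, 0.286 and 0.1591. The cause was not tested. Shares with the same sign in set 2 were 85.99% for nfrkb1/2/3, 83.4% for uch1/2 and 78.58% for the atx4/5;jmj24 label with equal library totals, and 84.26% and 77.93% for the last 2 with quantile normalization.

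Leaving out a library left 1 in its group, which the fit assumed to vary like the other groups. In LD the counts of calls ran from 1039 to 1554 for the arp5 label, 4718 to 6190 for uch1/2, 1793 to 2416 for the atx4/5;jmj24 label, 12 to 30 for INO80FL and 4503 to 5126 for INO80C. In SD of set 1 they ran from 1750 to 2883 for the arp5 label, 5367 to 6687 for nfrkb1/2/3, 4342 to 5230 for the atx4/5;jmj24 label, 15 to 77 for INO80FL and 3842 to 4667 for INO80N. In set 2 they ran from 1534 to 1862 for ino80, 3824 to 5052 for nfrkb1/2/3, 1688 to 2036 for uch1/2, 336 to 407 for the atx4/5;jmj24 label and 5 to 8 for INO80FL. Against ino80 they ran in LD from 5052 to 6648 for INO80FL, 3958 to 5520 for INO80N and 2703 to 3601 for INO80C, in SD of set 1 from 4454 to 5627, 1247 to 2288 and 283 to 1294, and from 1070 to 1862 for INO80FL in set 2. INO80N against INO80C ran from 3015 to 3486 in LD and 749 to 1098 in SD. Interactions ran from 851 to 1488 in ino80, 0 to 25 in the arp5 label, 720 to 1169 in nfrkb1/2/3, 1256 to 2308 in uch1/2 and 880 to 1694 in the atx4/5;jmj24 label.

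Calls shared with ino80, with 1 library left out, ran in LD from 858 to 1733 for the arp5 label, 929 to 1529 for the atx4/5;jmj24 label, 2005 to 2817 for INO80N and 2369 to 3126 for INO80C. In SD they ran from 1521 to 2992 for the arp5 label, 2856 to 3896 for the atx4/5;jmj24 label and 2847 to 3803 for INO80N. Across the sets they ran from 778 to 1074 for the arp5 label, 1054 to 1882 for nfrkb1/2/3, 1129 to 2020 for uch1/2, 639 to 1087 for the atx4/5;jmj24 label, 805 to 1278 for INO80N and 996 to 1787 for INO80C. Slopes in LD ran from 0.508 to 0.553 for the arp5 label, 0.759 to 0.808 for nfrkb1/2/3, 0.844 to 0.892 for uch1/2 and 0.375 to 0.422 for the atx4/5;jmj24 label, and in SD from 0.564 to 0.623 for the arp5 label, 0.887 to 0.929 for uch1/2, 0.477 to 0.542 for the atx4/5;jmj24 label and 0.587 to 0.644 for INO80N. Covariances ran from 0.1721 to 0.2456 for the arp5 label, 0.2699 to 0.3332 for nfrkb1/2/3, 0.3007 to 0.3699 for uch1/2 and 0.1606 to 0.2303 for the atx4/5;jmj24 label. Shares with the same sign in set 2 ran from 80.78% to 86.86% for ino80, 81.98% to 86.68% for nfrkb1/2/3, 78.15% to 84.75% for uch1/2, 71.64% to 78.62% for the atx4/5;jmj24 label and 81.25% to 96.88% for INO80FL.

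Depth limits the low genes. A value of 1 stands for about 1 read, so folds of genes at a few reads rest on counting error and on the pseudocount, and most false calls in the simulated data had a mean under 1.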

Other observations

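The tests on the INO80N gene classes were fixed before their results were seen, and the test on genes that differ between INO80FL and wild type was chosen only after.

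In its slope over the genes used to measure restoration, INO80N lay between wild type and ino80. This does not hold for all its changes. Of its 6352 calls against wild type in LD, 3107 were shared with ino80 in direction and 244 were opposite. Most auxin genes in INO80N lay above both wild type and ino80 in LD. The question was whether INO80N restores a particular class of the ino80 genes, although its slope alone does not show restoration. One hypothesis held that the genes it moves towards wild type are those that also change in libraries labelled arp5, so that their slope would be lower by more than 0.1. In LD, the slope on ino80 was 0.716 in the 1405 genes shared with the arp5 label and 0.472 in the other 1967. The difference of 0.243 (SD of single-library slopes 0.029, range 0.194 to 0.282) goes the opposite way, so these data argue against the hypothesis. INO80C gave 0.730 and 0.804 on the same classes, a difference of -0.073 (SD 0.04), and INO80FL 0.081 and 0.072. INO80N may instead act more on genes that were not called in the arp5 label, a hypothesis that came from this same test.

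A second hypothesis held that INO80N moves the genes that also change in the atx4/5;jmj24 label, with the same prediction in both day lengths. The slope was 0.541 in 562 shared genes and 0.631 in 2840 others in LD, and 0.546 and 0.652 in SD. The differences were -0.09 (range -0.134 to -0.048) and -0.106 (range -0.153 to -0.08). Both ranges lie below 0. SD passed the bound of 0.1 and LD missed it by less than its SD of 0.033, so whether the difference reaches that bound in LD stays undecided. INO80C gave 0.016 and 0.029.

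Besides INO80, 8 genes were called in INO80FL against wild type in all 3 comparisons. They are AT1G64795, AT3G05945, QQS, AT4G16442, AT5G15420, AT5G24240, AT5G63680 and ACR1, and all but QQS and ACR1 were chosen after their values were seen. If the ino80 stock carries differences that a transgene does not change, at least 4 should be called in the same direction in ino80, INO80N and INO80C in LD, and 5 were. The bound was set after the values were seen, and all these lines are compared with the same 2 wild-type libraries. Of the 5, ACR1, AT1G64795 and AT3G05945 were called lower outside that stock as well. ACR1 changed by -3.47 in INO80FL in LD, -3.37 in INO80N and -3.98 in INO80C, against -0.38 in the arp5 label, -1.45 in nfrkb1/2/3 (adjusted p = 2.8e-04), -1.69 in uch1/2 (adjusted p = 5e-05) and -0.19 in the atx4/5;jmj24 label. AT1G64795 changed by -6.77 in the arp5 label, -5.99 in nfrkb1/2/3, -6.77 in uch1/2 and -5.95 in the atx4/5;jmj24 label, against -5.77 in ino80. AT3G05945 changed by -4.89 in the arp5 label, -3.28 in uch1/2 and -6.53 in the atx4/5;jmj24 label, against -1.11 in ino80. In nfrkb1/2/3 AT3G05945 went the other way, by 1.01 (adjusted p = 0.068). AT4G16442 changed by -3.09 in ino80 and by 0.05 in the arp5 label, -0.20 in nfrkb1/2/3, -0.12 in uch1/2 and 0.08 in the atx4/5;jmj24 label. AT5G63680 changed by -1.15 in ino80 and by 0.03, 0.24, 0.36 and 0.04 in the same 4 lines. The count of 5 therefore does not separate a background of the stock from other causes, and the cause is left open.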
